A study of Homo sapiens with 62 samples.

How the data were processed

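The libraries came from GM12878, an Epstein-Barr virus-immortalised human B-lymphoblastoid cell line. Cells were picked by hand, lysed and amplified to cDNA with a SMARTer kit, and the cDNA was fragmented and tagged with Nextera and sequenced on a HiSeq 2000, per the labels' protocols. Of the 62 samples, 20 were analysed here. They were pools of 10 cells divided into 10 parts that were then handled like single cells. The other 42 samples, among them picked cells, larger pools and diluted total RNA, were not analysed here. For 34 of those the labels gave no group.

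The 20 libraries formed 2 sets of 10. In the numbered set the titles count the splits from 1 to 10, and in the unnumbered set they give only a library number (232, 233 and 246 to 253). The labels do not state outright that each set came from a single pool. The libraries were put into 4 runs of consecutive laboratory experiment numbers. Run a held numbered splits 5 to 8, run b the other 6 numbered splits, run c unnumbered splits 232 and 233, and run d the other 8. Other samples of the study fill the numbers between runs b, c and d, so these belong to a single series, and run a lies apart from it. The titles of run b also give library numbers, which leave a gap where splits 5 to 8 would fall. Those of run a give none. The experiment numbers thus set run a apart, but whether it was a separate batch is not given. P-values of single genes and of libraries measure the spread between splits of a set, which is technical only if the set came from a single pool, and not the spread between cells or cultures. For gene lists, the camera test described below also sets a list against other genes. The test of the CV of lists does only that, over random lists, and genes are not independent replicates.

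Each deposited file held FPKM (fragments per kilobase and per megafragment mapped, or M) for 55040 annotated genes with a lower and an upper confidence bound and a status. The authors made these values with TopHat 1.4.1 and Cufflinks 2.0.2, per the submitters' processing notes. The genome build of these 20 files is not given in the sources used here. The label of other libraries of the series names hg19 and GENCODE 13, and coordinates below are those of the deposited files, counted from 1. Rows with status LOWDATA in every library (5797, median locus of 131 bases) and rows with status FAIL in at least 1 library (128) were left out. This left 49115 rows. Among the rows that failed were EEF1A1, HSPA8, TK1 and NUSAP1.

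FPKM hides the number of fragments, but the bounds keep it. For 10 mitochondrial protein genes the upper bound lies 2 square roots of the fragment number above the value, and a line through these numbers against gene length gave the depth. The largest residual was 0.234%. Depth estimated in this way was 11.8 to 20.6 M fragments in the numbered set. In the unnumbered set it was 23.3 to 38.7 M, except for 7.80 M in split 252 and 0.128 M in split 247. At 0.128 M fragments a single fragment on a transcript of 1 kilobase already exceeds the detection threshold, so the lowest levels of that library carry little information. Gene types, transcript lengths and GC content came from GENCODE 29. Of the file's identifiers 48871 matched it directly and 1969 more matched by symbol. A length was found for 10306 of the 10506 tested genes.

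Everything after FPKM was computed here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1. A gene counted as detected at an FPKM of 1 or more. The dropout midpoint was the level at which a logistic curve of detection (FPKM above 0) on the log10 mean of the other 9 libraries of the set crosses 0.5. Library means were compared with 2-sided permutation tests of 100000 resamples, or exact ones below 10 libraries per group. Correlation used log2(FPKM + 1) over genes with a mean of 1 or more. The coefficient of variation (CV) was taken over the 10 libraries of a set. Gene differences were tested with limma (trended variance) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05, so that a fold change understates the change of low genes. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and CV of lists against 10000 random lists matched on level in 20 bins. The 24 lists were fixed before the data were examined, as were the groups, tests, alternatives and the rule for naming genes.

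That rule named the 12 largest changes in each direction among genes past the threshold with FPKM of 1 or more in at least 8 of the 10 libraries of the higher set. It also took, from each list, the 2 most abundant members and up to 2 members with the smallest p, then the 10 most abundant genes, and the 6 most and 6 least variable among genes at 100 FPKM or more in both sets. This left 102 genes after 1 that is not reported here was set aside. Y-linked genes and XIST were not named. An exact 0 may be a failed capture, so sets with zeros are described by medians, ranges and counts of libraries.

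The alternatives were other thresholds, pseudocounts and filters, rescaling to TPM or by median-ratio size factors (0.764 to 1.52), an exact rank-sum test per gene, run a as a covariate, runs b, c and d alone, and leaving out each library. Added after seeing the data were fits without splits that stood apart, protein-coding genes alone, corrections for transcript length and GC content, and log2 depth as a covariate. The limma step was tested on simulated random counts of 10506 genes, of which 200 with a mean of 30 FPKM or more were changed. It recovered 4.62% of 2-fold, 10.9% of 4-fold and 36.6% of 8-fold changes, and 2 of its 38 calls were unchanged genes. Random counts are simpler than these libraries, so the rates need not hold for them or for lower genes. The midpoint fit recovered 99.0 to 104% of the simulated levels.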

Results

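The series recorded transcript levels in GM12878 cells by SMART-seq, and its splits of 10-cell pools were made to assess technical variation. Splits of the same pool hold RNA that was mixed before it was divided, so differences between them arise in handling, capture, amplification and sequencing. The labels do not state that each set compared here came from a single pool. Values were available for 10 numbered and 10 unnumbered splits, at estimated depths of 16.4 ± 3.29 megafragments (M) (SD, n = 10) in the numbered set and 0.128 to 38.7 M in the unnumbered set. Summed over genes, the mitochondrial genome held 3.37 to 6.32% of the FPKM in the numbered set and 6.18 to 8.17% in the unnumbered set. No pair of libraries held identical values.

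Immunoglobulin light chain, actin and thymosin rows were among the most abundant. The light chain constant genes IGLC2 and IGLC3 and the variable gene IGLV2-23, the beta-actin gene ACTB, the thymosin gene TMSB4X, the MHC class I light chain gene B2M and the ribosomal protein gene RPL14 were among the 10 genes with the highest mean FPKM. MT-CO2, which encodes a mitochondrial cytochrome oxidase subunit, stood at 10290 ± 2830 FPKM in the numbered set and 14930 ± 2460 FPKM in the unnumbered set (SD, n = 10). The difference in ACTB did not pass, at 18660 ± 4642 and 23410 ± 12400 FPKM (limma adjusted p = 0.533), and split 247 alone reached 57224 FPKM. The highest value of all, 87680 ± 12740 FPKM in the numbered set, belonged to TMSB4XP6, a pseudogene of TMSB4X of which reads cannot be separated from its parent with certainty. Likewise IGLC2 and IGLC3 share nearly identical sequence, so their separate values are uncertain. J01415.25, a mitochondrial row that overlaps other mitochondrial genes, was also in this group.

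The numbered splits detected more genes than the unnumbered ones. At FPKM 1 or more they held 5357 ± 1085 genes, and the unnumbered splits 4328 ± 533 genes (SD, n = 10), a difference of 1029 genes (2-sided permutation p = 0.00646). A set of 816 genes was detected in all 20 libraries. In the numbered set 1389 genes were detected in all 10 splits, 12614 in at least 1 and 3436 in exactly 1, and in the unnumbered set 1052, 10598 and 3053. Numbered splits 7 and 8, both of run a, held 7671 and 6611 genes, while numbered split 9 held 3771 and unnumbered split 253 held 2942. The 6 numbered splits of run b held 4817 ± 610 genes, which exceeded the unnumbered set by 489 genes (exact permutation p = 0.0987), so the call was lost without run a. Within the numbered set, the 4 splits of run a held 6167 ± 1206 genes (exact permutation p = 0.0571 against run b). With the authors' lower confidence bound above 0 as the criterion the difference was 1359 genes (p = 0.0612).

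**Figure D1:**
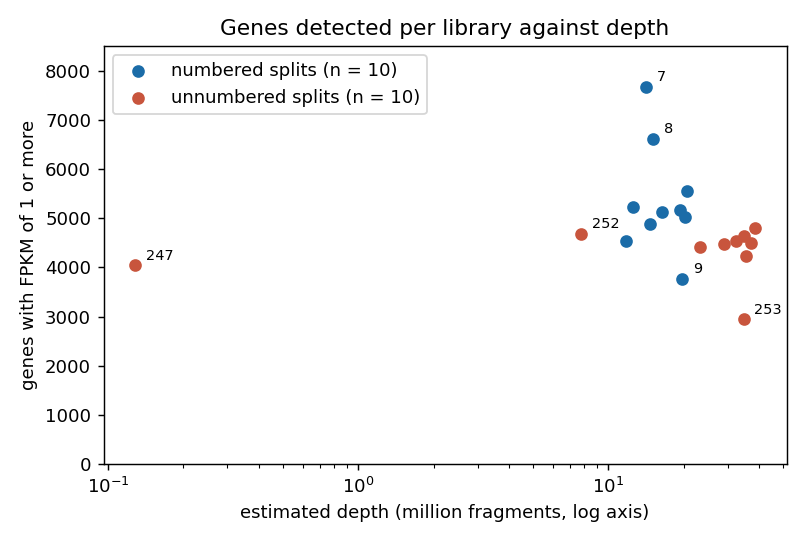
Genes with FPKM of 1 or more (vertical axis) against estimated depth in M fragments (log axis) for the 10 numbered (blue) and 10 unnumbered (red) splits, each point a library. Split 247, at 0.128 M fragments, held 4049 genes, and splits 9 and 253 held 3771 and 2942.

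No relation between depth and detection passed within the sets. Pearson's r between depth and genes detected was -0.251 in the numbered set (permutation p = 0.503, adjusted 0.788) and 0.00152 in the unnumbered set (p = 0.747, adjusted 0.788), over 10 libraries each. Spearman's rho was -0.0424 (p = 0.918, adjusted 0.918) and 0.297 (p = 0.411, adjusted 0.819). Without the 2 libraries farthest from the median depth, r was -0.306 and -0.00409. These are 2 of 4 relations computed. In split 247, a value of 1 FPKM needs less than 1 fragment per kilobase, so its count of 4049 genes is not on the same footing as that of deeper libraries.

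The level at which 50% of genes were seen depended on what counted as seen. FPKM above 0 also counts values far below 1 fragment, such as 5.67e-259 FPKM of ARPC1A in numbered split 9. Midpoints by that criterion went down to 0.0008 FPKM in numbered split 7 and 0.0018 FPKM in unnumbered split 233. They are therefore not levels at which transcripts were captured. With any FPKM above 0 the midpoint was 0.173 ± 0.141 FPKM in the numbered set and 1.66 ± 4.99 FPKM in the unnumbered set, the latter carried by 15.9 FPKM in split 247, and the log2 difference was 0.05 (permutation p = 0.979). That difference moved to 1.20 without split 247 (permutation p = 0.331) and to -0.17 to -0.50 when 1 numbered split was left out. Leaving out a split also takes it out of the mean that sets the level of each gene in its set. Since any numbered split had this effect, the shift need not come from particular splits. With FPKM of 1 or more it was 21.0 ± 16.2 and 35.0 ± 28.4 FPKM, lower in the numbered set by a log2 difference of -0.86 (p = 0.0572), and with 0.1 or more by -1.14 (p = 0.0401). At 10 to 30 FPKM a gene was therefore often listed in some splits of a set and not in others.

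Correlation between splits was computed over 10506 genes. The median Pearson r across genes was 0.602 over the 45 numbered pairs, 0.571 over the 45 unnumbered pairs and 0.539 over the 100 pairs across sets. Genes are not independent replicates and pairs share libraries, so no test was made. Split 9 had the lowest mean r with its own set among the numbered splits, 0.554 against 0.5945 or more, and split 253 among the unnumbered ones, 0.538 against 0.554 or more. Averages of 5 splits correlated at 0.722 with averages of the other 5 in the numbered set, at 0.704 in the unnumbered set and at 0.645 across sets. Averages of all 10 correlated at 0.681 across sets.

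The spread between splits fell as the level rose. At 1000 FPKM or more the median CV was 0.234 over 224 genes in the numbered set and 0.266 over 202 genes in the unnumbered set. At 30 to 100 FPKM it was 1.17 and 1.4, and at 1 to 3 FPKM it was 2.48 and 2.83. With 10 libraries the CV has a ceiling, which a gene seen in only 1 library reaches. The upper quartiles at 1 to 3 FPKM, 3.11 and 3.15, lay near it, so the CVs of low genes are capped. Over all genes of 10 FPKM or more the median was 1.27 (jackknife SE 0.0715) and 1.45 (SE 0.0602). Among genes at 100 FPKM or more in both sets, the least variable were TMSB4X (mean CV 0.140), RPL21 (0.142), RPL41 (0.143), RP11-565J7.3 (0.146), HLA-DRA (0.149) and RP11-613M5.2 (0.151). The most variable were CTD-2012J19.2 (2.5), GNRHR2 (2.45), VIMP (2.25), MSRB1 (2.24), AL353629.1 (2.17) and IMMP1L (2.05). MSRB1, a methionine sulfoxide reductase gene, was listed at 0 in 4 numbered and 7 unnumbered splits and reached 5699 and 8318 FPKM in single ones.

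**Figure D2:**
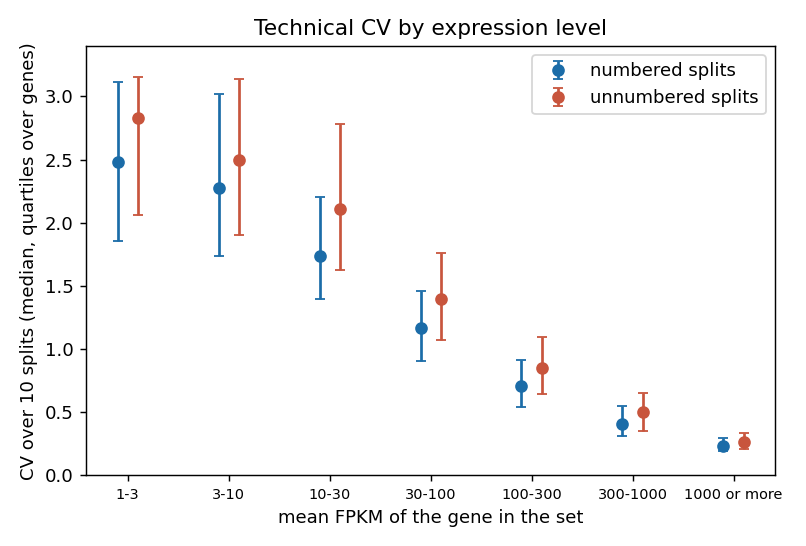
Median CV over the 10 splits of a set (points) with quartiles over genes (bars) by bin of mean FPKM, for numbered (blue) and unnumbered (red) splits. The medians fall from 2.48 and 2.83 at 1 to 3 FPKM to 0.234 and 0.266 at 1000 FPKM or more.

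Cytosolic ribosomal protein genes had a lower CV than random lists drawn from the same 20 bins of level, in both sets. Their median CV was 0.202 in the numbered set and 0.243 in the unnumbered set, 52 genes each. No random list was lower (random-list test, adjusted p = 0.0044 and 0.0042). These p-values are over lists of genes, not over splits. The bins hold equal numbers of genes, and only 224 and 202 genes reached 1000 FPKM, so the highest bin also held lower genes. The list had median levels of 3644 and 1938 FPKM, and CV falls with level. Whether it varied less than genes of like level was therefore not settled. Over all genes at 1000 FPKM or more the median CV was 0.234 and 0.266. In the unnumbered set the list of sequence-specific transcription factors of B cells was also below its matched lists, at a median CV of 1.61 over 19 genes (adjusted p = 0.0147, and 0.103 in the numbered set). The difference between the sets was not tested. No other list passed, of 22 in the numbered set and 21 in the unnumbered set, and with the SD of log2(FPKM + 1) as the measure the transcription factor list was lost in the unnumbered set (adjusted p = 0.127).

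Between the sets, the NF-kB, interferon-response and MHC lists were higher in the numbered splits by camera, and the immunoglobulin, unfolded protein and G2/M lists were higher in the unnumbered splits, although most single genes of these lists did not pass. Of 10506 genes, 558 passed an adjusted p of 0.05 by limma, 413 higher in the numbered and 145 higher in the unnumbered splits. The median log2 difference of all genes was 0.35, and 0.21 with size factors, and differences are to be read against that shift. The deposited values are also on unequal scales. Summed FPKM was 1471330 ± 199456 in the numbered and 1215430 ± 47042 in the unnumbered set (SD, n = 10). The split into directions moved with scaling, to 316 and 200 genes with size factors, to 341 and 223 with TPM and to 220 and 262 once a trend on transcript length was removed. With splits of runs b, c and d alone 359 genes passed, with protein-coding genes alone 319, and an exact rank-sum test per gene called 953, of which 522 were among the 558. The experiment numbers of runs b, c and d belong to a single series, which thus holds both sets, but batches of preparation are not given in the sources used here.

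Of the 12 largest differences with higher levels in the numbered splits, 5 were of chemokine genes on chromosome 17. CCL4, a macrophage inflammatory protein that attracts T cells (chromosome 17, 34431220 to 34433014), ranged from 77.3 to 2003 FPKM in the 10 numbered splits and was listed at 0 in 9 unnumbered splits and at 0.198 FPKM in the other (log2 difference 9.13, SE 0.62, adjusted p = 7.25e-10). CCL3 (34415602 to 34417515) had medians of 810 and 0.0229 FPKM (8.04, adjusted p = 4.71e-07). Their near-identical copies CCL3L1, CCL4L1 and CCL4L2 moved likewise, by 6.86, 7.12 and 7.35, but share reads with the parent genes. CD82, a tetraspanin, had medians of 192 and 0.00532 FPKM (7.08, adjusted p = 6.57e-08). IL32, a cytokine, differed by 6.93 and ISG15, an interferon-induced ubiquitin-like protein, by 6.81. SNORD13, a small nucleolar RNA, RN28S1, a ribosomal RNA row, and the noncoding or pseudogene rows RP11-329L6.1 and RP11-345J4.6 completed these 12, with differences of 10.34, 7.13, 8.70 and 6.94. All 12 passed 1 FPKM in all 10 numbered splits and were listed at 0 in at least 3 unnumbered ones.

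In the other direction, IGJ, which encodes the joining chain of polymeric antibodies (chromosome 4, 71521258 to 71547534), ranged from 190.0 to 828 FPKM in the unnumbered splits and passed 1 FPKM in 4 numbered splits (log2 difference -6.33, SE 1.0, adjusted p = 1.03e-04). CXCL10, an interferon-induced chemokine (76942273 to 76944650), was listed at 0 in all 10 numbered splits and passed 1 FPKM in 9 unnumbered ones, at a median of 170 FPKM (adjusted p = 4.35e-04). HSPA5, the endoplasmic-reticulum chaperone BiP, had medians of 0.185 and 139 FPKM (-5.49, adjusted p = 4.07e-05). The mitotic kinase gene AURKA (-4.93), the condensin subunit gene NCAPH (-4.87) and the spindle midzone gene PRC1 (-4.64) were higher in the unnumbered splits. So were VPS45 (-5.42), ARPC1A (-5.19), CWF19L1 (-4.93), MT1E (-4.71), TPRG1 (-4.71) and GPN1 (-4.61), although GPN1 was lost with run a as a covariate (adjusted p = 0.0917). In the lower set, several of these genes held values near 0 in most splits and high values in single ones, such as 120.15 FPKM of GPN1 and 105 FPKM of CWF19L1.

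**Figure D3:**
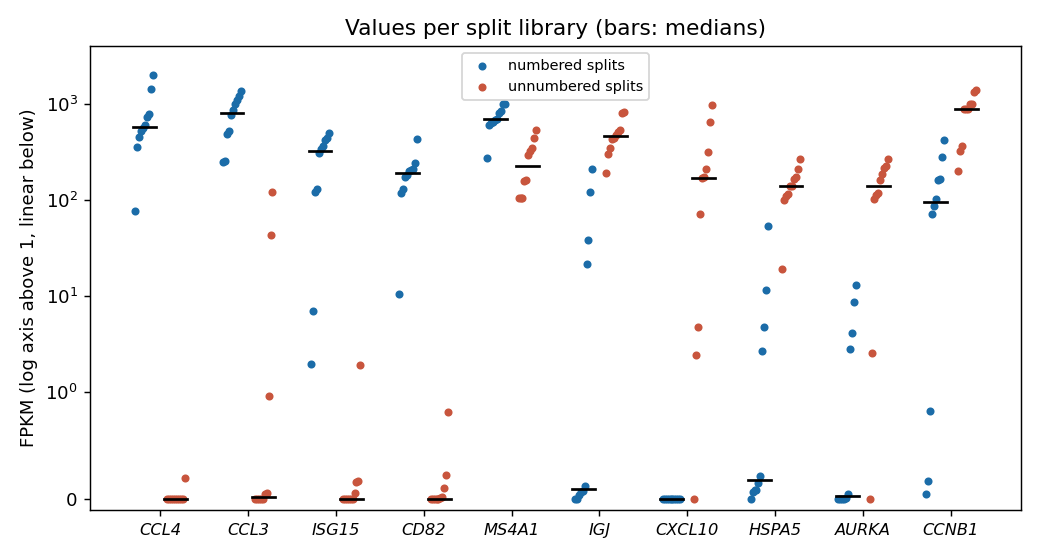
FPKM per split library (log axis above 1, linear below) for 10 named genes in numbered (blue) and unnumbered (red) splits, with black bars at the medians. CCL4 was listed at 0 in 9 unnumbered splits and CXCL10 at 0 in all 10 numbered splits.

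By list, 17 of 22 passed camera, 10 higher in the numbered and 7 higher in the unnumbered splits. With an estimated correlation 15 passed, all but nuclear-encoded oxidative phosphorylation and immediate early genes. The smallest camera adjusted p was then 6.96e-05, of the immunoglobulin list, so the smaller values below depend on the preset correlation. NF-kB and EBV-associated activation genes had a median log2 difference of 1.76, with 8 of 26 genes past the threshold, all higher in the numbered splits (camera adjusted p = 7.97e-06). Adjusted over the list alone, 12 were higher and 1 lower. CCL3 and CCL4 led it. CCL22, at 766 ± 222 and 565 ± 226 FPKM, and the lymph node homing receptor gene CCR7, at 484 ± 237 and 1040 ± 513 FPKM, did not pass (adjusted p = 0.368 and 0.069), although with size factors CCR7 passed as higher in the unnumbered splits (-1.32, adjusted p = 0.0274). Interferon response genes had a median of 1.52 with 4 of 24 higher in the numbered splits, and 5 adjusted over the list alone (adjusted p = 1.53e-05). IFITM1 stood at 2058 ± 357 and 423 ± 190 FPKM (2.47, adjusted p = 3.34e-06), while MX1 did not pass (adjusted p = 0.174).

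Antigen presentation followed the same direction. MHC class II genes had a median of 1.30 with 5 of 14 genes higher in the numbered splits, and 7 adjusted over the list alone (camera adjusted p = 3.65e-04). With size factors 3 passed, and with the length trend removed the median fell to 0.76. The invariant chain gene CD74 stood at 5222 ± 1077 and 2328 ± 653 FPKM, and HLA-DRA at 4292 ± 684 and 2437 ± 340 FPKM (adjusted p = 2.16e-05 and 1.61e-05). Once a trend on transcript length was removed, HLA-DRA was no longer past the threshold (adjusted p = 0.298). MHC class I genes had a median of 1.05 with 2 of 15 higher, and 4 adjusted over the list alone (adjusted p = 0.00278), among them B2M at 27490 ± 4870 and 14900 ± 2292 FPKM and HLA-F. B2M was no longer past the threshold once the length trend was removed (adjusted p = 0.292), and HLA-B did not pass (adjusted p = 0.0766). B cell identity genes had a median of 1.22 with 4 of 21 higher, and 5 adjusted over the list alone (adjusted p = 0.0228), and without run a the median fell to 0.716 (adjusted p = 0.0415). The CD20 gene MS4A1 stood at 716 ± 209 and 258 ± 155 FPKM (1.64, adjusted p = 0.00401), and the B cell receptor gene CD79A differed by 4.69 (adjusted p = 0.00274). BLNK did not pass (adjusted p = 0.765).

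Immunoglobulin and plasmablast genes had a median of -1.20, with 5 of 13 higher in the unnumbered and 1 higher in the numbered splits, and 6 and 1 adjusted over the list alone (camera adjusted p = 2.78e-09). IGLC2 stood at 18120 ± 2836 and 42850 ± 11040 FPKM, a ratio of 2.37, and IGLV2-23 at 8065 ± 1410 and 18780 ± 4809 FPKM. Unfolded protein response genes had a median of -1.12 with 3 of 14 higher in the unnumbered splits, and 4 adjusted over the list alone (adjusted p = 1.43e-04). The chaperone genes CALR and HSP90B1 stood at 128 ± 46.4 and 463 ± 181 FPKM and at 122 ± 41.5 and 395 ± 141 FPKM (adjusted p = 0.00134 and 0.00322). G2/M genes had a median of -1.4 with 5 of 26 higher in the unnumbered splits, and 6 adjusted over the list alone (adjusted p = 1.25e-07). Without splits 9, 247 and 253, 2 genes passed. The cyclin gene CCNB1 stood at 129 ± 136 and 825 ± 407 FPKM (-4.25, adjusted p = 0.00903). CKS2 and PTTG1 did not pass (adjusted p = 0.148 and 0.849), although CKS2 did with the length trend removed (adjusted p = 0.0065). S phase genes had a median of -0.72 with 1 of 21 higher, FEN1, and 1 adjusted over the list alone (adjusted p = 0.00171). FEN1 was lost with run a as a covariate (adjusted p = 0.127), while PCNA and RRM2 did not pass (adjusted p = 0.883 and 0.818).

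Ribosomal protein genes were the most uniform list, with 47 of 52 higher in the numbered splits and none lower, and 51 adjusted over the list alone (median 1.0, camera adjusted p = 1.04e-65). RPS29 stood at 11490 ± 2007 and 3754 ± 710 FPKM (1.62, adjusted p = 7.25e-10) and RPS23 at 8280 ± 1341 and 3500 ± 684 FPKM. RPS18 (0.90, adjusted p = 1.72e-06) was lost once the length trend was removed (adjusted p = 0.401). The median was 0.76 with size factors and 0.45 once a trend on transcript length was removed. The pseudogene share of summed FPKM was 18.5 ± 0.711% in the numbered and 12.9 ± 1.28% in the unnumbered set. Mitochondrially encoded genes went the other way, with 7 of 12 higher in the unnumbered splits and 9 adjusted over the list alone (median -0.59, adjusted p = 2.61e-12). With this list's estimated correlation of 0.47 the camera adjusted p was 0.0190. MT-CO1 stood at 4155 ± 1287 and 10160 ± 1338 FPKM (-1.34, adjusted p = 2.08e-07) and MT-ND1 at 754 ± 313 and 2159 ± 519 FPKM (-1.63), while MT-CO2 was lost with run a as a covariate (adjusted p = 0.131). Nuclear-encoded oxidative phosphorylation genes had a median of 0.54 with 4 of 34 higher in the numbered splits, and 6 adjusted over the list alone (adjusted p = 0.0171), which was lost with an estimated correlation (adjusted p = 0.224), with size factors (adjusted p = 0.230) and with the length trend removed (adjusted p = 0.833), where its median turned to -0.07. COX7C, ATP5L and COX5A were among the 4, of which ATP5L was lost with size factors (adjusted p = 0.212) and with the length trend removed (adjusted p = 0.449), and COX7C with the length trend removed (adjusted p = 0.0522).

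Proteasome genes had a median of -0.59 (camera adjusted p = 1.01e-05) and splicing factor genes of -0.33 (adjusted p = 0.00496), each with 1 gene higher in the unnumbered splits, also when adjusted over the list alone. These were PSMB4, at 220 ± 133 and 1084 ± 360 FPKM, and SRSF6, at 61.7 ± 43.4 and 442 ± 161 FPKM. PSMB3, PSMA2, HNRNPA1 and SNRPD1 did not pass, although PSMB3 did with the length trend removed (adjusted p = 0.019) and HNRNPA1 with size factors (adjusted p = 0.0409), both higher in the unnumbered splits. Cholesterol synthesis genes had a median of 1.36 with 2 of 20 higher in the numbered splits, HMGCS1 among them, and 3 adjusted over the list alone (adjusted p = 0.00506). Neither passed without splits 9, 247 and 253. HMGCS1 was lost with run a as a covariate (adjusted p = 0.334) and with size factors (adjusted p = 0.0527). FDPS and EBP did not pass. Replication-dependent histone genes had a median of 1.89 with 2 of 12 higher in the numbered and 1 higher in the unnumbered splits, and 6 and 1 adjusted over the list alone (adjusted p = 0.0228). That 1 was HIST1H4C, the most abundant member, at 6690 ± 1706 and 10600 ± 1782 FPKM (-0.70, adjusted p = 0.00176), whereas HIST1H1E differed by 5.31 and HIST1H1C did not pass (adjusted p = 0.163). The list was lost once the length trend was removed (adjusted p = 0.143) and with runs b, c and d alone (adjusted p = 0.0782). Immediate early and stress genes had a median of 0.90 with 1 of 13 higher, DUSP2, and 4 and 1 adjusted over the list alone (adjusted p = 0.0469). They were lost with an estimated correlation (adjusted p = 0.0547), with a pseudocount of 0.1 (adjusted p = 0.0517) and without splits 9, 247 and 253 (adjusted p = 0.0503). DUSP2 was listed at 0 in all 10 unnumbered splits. MYC and HSPH1 did not pass (adjusted p = 0.0564 and 0.0781), although HSPH1 did with size factors as higher in the unnumbered splits (adjusted p = 0.0457).

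**Figure D4:**
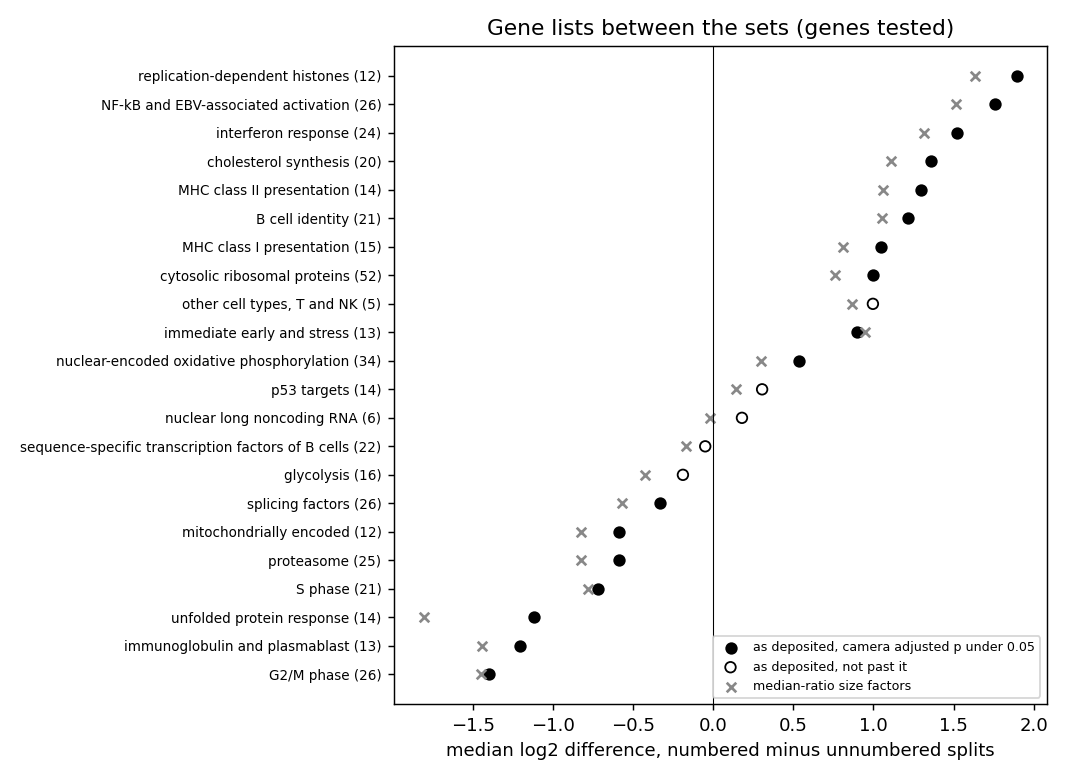
Median log2 difference (numbered minus unnumbered splits, horizontal axis) of 22 gene lists as deposited (circles, filled where the camera adjusted p was under 0.05) and with size factors (crosses), with the number of genes tested in brackets. NF-kB genes lie at 1.76 and G2/M genes at -1.4.

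The remaining lists did not pass. Glycolysis genes had a median of -0.19 and a camera adjusted p of 0.294, which became 0.0495 with size factors, and 2 of 16 genes were higher in the numbered and 1 higher in the unnumbered splits, each 2 adjusted over the list alone. The former were GAPDH and ALDOA. GAPDH was lost with size factors (adjusted p = 0.210), with run a as a covariate (adjusted p = 0.0542) and with the length trend removed (adjusted p = 0.857), ALDOA with the length trend removed (adjusted p = 0.208), and TPI1 did not pass, although it did with the length trend removed as higher in the unnumbered splits (adjusted p = 0.0371). The list's median turned to 0.079 without run a. The p53 targets had a positive median (0.31) and mean (0.36) while camera put them below other genes (adjusted p = 0.974), and MDM2 and FAS did not pass, nor any of the 14 genes over all genes or adjusted over the list alone. Transcription factors of B cells had a median of -0.05 and a mean of 0.36 (adjusted p = 0.736), with BATF higher in the numbered splits (5.09) and IRF4 higher in the unnumbered ones (-1.94), 3 and 1 adjusted over the list alone, and MEF2C not past the threshold (adjusted p = 0.460). The list named nuclear long noncoding RNA (median 0.18, adjusted p = 0.242) held 2 of 6 genes higher in the numbered splits. These were GAS5 and SNHG5, also adjusted over the list alone. Its member NEAT1 was left out for status FAIL in 14 libraries, and the location of these RNAs in the cell was not measured. GAS5 was lost with run a as a covariate (adjusted p = 0.0786), and the list's median turned to -0.02 with size factors and to -0.30 without run a. Markers of T and NK cells did not pass (median 1.0, 5 genes, adjusted p = 0.165), with 0 genes over all genes and 1 adjusted over the list alone, and NKG7 and CD2 were each listed at 0 in 4 numbered splits and at 0 in 8 and 9 unnumbered ones. CD2 passed 1 FPKM in 6 numbered splits and 1 unnumbered split. Myeloid and epithelial lists had fewer than 5 tested genes. CSF1R averaged 5.09 FPKM over the 20 libraries, S100A9 0.137, CDH1 18.4 and KRT8 2.03. The means of S100A9 and KRT8 rest on single numbered splits, at 2.75 FPKM in split 8 and 40.7 FPKM in split 7. CSF1R reached 53.8 FPKM in numbered split 5.

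Runs within the numbered set were compared gene by gene over few libraries. Between run a (4 splits) and run b (6 splits) 1 of 9955 genes passed by limma, the long noncoding RNA gene PVT1, which was named after its value was seen (log2 difference 7.48, adjusted p = 0.0392). At an unadjusted p under 0.05 there were 492 genes, and the exact rank-sum test called 0, with 503 at an unadjusted p under 0.05. The smallest p of that test with 4 against 6 splits is 0.00476. Even if all 503 genes held it, none would pass after adjustment over 9955 genes. The call of 0 therefore says nothing about the runs. PVT1 was lost whenever 1 split was left out, and without split 10 a gene of the opposite sign passed.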

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

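The tests of transcript length, depth, run a and chance splits were chosen after the results were seen. The summed-pseudogene test was written before its result, and the share of pseudogenes beside it was added afterwards.

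Ribosomal protein genes were higher in the numbered splits, by a median log2 difference of 1.0. In these libraries transcript length as the whole cause is argued against, although part of the difference went with length. The median was 0.45 (95% bootstrap interval over the 52 genes 0.30 to 0.61) after a length trend was removed per library, against 0.05 for all genes. The bootstrap treats genes as independent and holds no spread between splits, so the interval is too narrow. Depth was tested without split 247, because with it the mean log2 depths of the sets are nearly equal (4.01 and 4.03) and the covariate hardly moves a gene (median 0.00235). Without it, the mean of the list differed by 0.99 (95% interval 0.74 to 1.25) with log2 depth as a covariate, and by 0.99 (0.517 to 1.47) without split 252 as well, against 1.07 and 1.09 with set alone, while the covariate moved all genes by a median of 0.35 and 1.14. A straight trend on log2 depth, shared by both sets, thus did not take up the difference. Set and depth are nonetheless not separated. Without splits 247 and 252 the depths do not overlap, at 11.8 to 20.6 M in the numbered and 23.3 to 38.7 M in the unnumbered set. Without split 247, split 252 at 7.80 M is the only unnumbered library below that range. Depth as the cause therefore stays open. Summing each of 45 genes with its 226 pseudogenes named by symbol gave 0.98 (0.81 to 1.19 by the same bootstrap over genes). This was a weak test, since these pseudogenes held a median of 0.0761% of the sum and those with clone names were not matched. A shift of reads to pseudogenes in the unnumbered splits would raise their share there, but pseudogenes named for ribosomal protein genes held 2.69 ± 0.129% of summed FPKM in the numbered and 1.71 ± 0.109% in the unnumbered splits (permutation p = 2e-05, the smallest that these permutations give). A difference in preparation between the sets, and one between the pools, stay open.

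The NF-kB, interferon and MHC lists were higher in the numbered splits, and the immunoglobulin, G2/M and unfolded protein lists in the unnumbered splits. Without run a the medians of these 7 lists kept between 0.834 (MHC class II) and 1.21 times their size, which argues against that run as the cause. A straight trend on log2 depth did not take up the differences of the NF-kB, interferon, immunoglobulin and G2/M lists. With log2 depth as a covariate the 95% intervals of the differences in list mean lay beyond 0 in the direction of each list. This held without split 247 (by 0.781 or more) and without splits 247 and 252 (by 0.270 or more). For both MHC lists and the unfolded protein list such a trend itself stays open. Their intervals lay beyond 0 without split 247 (by 0.216 or more) but included 0 without split 252 as well, with a bound of -1.14 for MHC class II. Depth as the cause stays open for all 7 lists, because set and depth are not separated in these fits. A difference in preparation and a difference between the pools stay open, since neither is given in the sources used here, and no biological explanation was tested. Of 100 divisions of the 20 libraries into 10 and 10, only 1, the real one, reached 17 lists, and the highest other gave 13.

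That count needs care, because 58 of the 99 other splits called at least 1 list, with a median of 1. Splits with unequal numbers of numbered libraries on their sides still carry part of the difference between the sets, and 49 of these 57 called a list. Of the 42 with 5 numbered libraries on each side 9 did, and the highest gave 4. Whether camera with a preset correlation calls too readily was not separated from this. For single genes, 1 of 100 splits, the real one, reached 558 genes, the highest other gave 16, and 10 of the 99 others called any. Both results argue against a random division of the libraries, at no finer than 1 in 100. They do not tell pool, preparation and depth apart. Between runs a and b, 9 of 100 splits gave at least the 1 gene of the real one, and the highest other gave 4, so chance was not excluded there.

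Some libraries lay far from the others of their set, by a gap to the nearest library that is large against the range. Chance gives about 1 in 20 such hits for values of a normal spread, and 8 of 18 library measures and 50 of 204 gene measures gave one. The rate was not measured for FPKM with many zeros, and some of the genes were chosen for their spread or for a set near 0, so their hits follow in part from that choice. Unnumbered split 253 detected 2942 genes and had a midpoint of 114 FPKM at FPKM 1. Unnumbered split 247, the shallowest, had 27.5% of FPKM in its 10 highest genes, 10.0% in pseudogenes and a midpoint of 15.9 FPKM for detection above 0. Numbered split 9 had 5.42% of FPKM in rows of low data, a mean correlation of 0.554 with its set and a midpoint of 62.5 FPKM at FPKM 1.

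Single unnumbered splits stood apart, in FPKM, for SNORD13 (2714), CCL4 (0.198), RP11-329L6.1 (1119), CCL3 (122), CCL4L2 (89.0), CCL4L1 (78.3), CD82 (0.821), RP11-345J4.6 (633), IL32 (240.2), CCL3L1 (0.938), ISG15 (1.92), NCAPH (353), TPRG1 (292), CD79A (110.4) and HLA-F (83.8). The same held for MX1 (445), RRM2 (574), HIST1H1C (478.5), HMGCS1 (113), NKG7 (243), CD2 (5.61), CDH1 (77.0), AL353629.1 (18120), MSRB1 (8318), VIMP (876) and CTD-2012J19.2 (1059). Split 247 alone gave IGLC2 (70411), IGLC3 (41624), IGLV2-23 (31474), ACTB (57224) and GNRHR2 (1556). Single numbered splits stood apart for CCL4L2 (1661), CCL4L1 (1196), HSPA5 (54.2), VPS45 (1.35), ARPC1A (43.7), CWF19L1 (105), NCAPH (69.5), MT1E (35.2), TPRG1 (25.3), GPN1 (120.15), IRF4 (200.4), MEF2C (426), NKG7 (92.2), CSF1R (53.8), S100A9 (2.75), KRT8 (40.7), IMMP1L (933), MSRB1 (5699) and VIMP (5007).

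Outside the values compared, rows with status LOWDATA in every library held a mean of 2.82% of summed FPKM. EEF1A1, which encodes a translation elongation factor and had status FAIL in 6 libraries, had a median of 3909 FPKM.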

How the results depend on the processing

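Tests added after seeing the data were the fits without splits that stood apart, on runs b, c and d alone for detection and lists, on protein-coding genes, with length or GC trends removed, and with depth as a covariate. No paired analysis was possible because the 2 sets compared share no replicate numbers. The difference in genes detected kept its direction under all alternatives run, at 1359 genes with the lower confidence bound (p = 0.0612) and 489 with runs b, c and d (p = 0.0987), where it was not past the threshold, and at 772 to 1205 when 1 library was left out. The log2 difference in dropout midpoint reversed to -1.14 at FPKM 0.1, to -0.86 at FPKM 1 and to -0.19 for genes with a set mean of 0.1 or more, and ranged from -0.50 to 1.20 when 1 library was left out, below 0 without any single numbered split. The cause was not tested. Median correlations for numbered, unnumbered and across-set pairs became 0.550, 0.532 and 0.495 with a pseudocount of 0.1, 0.534, 0.517 and 0.471 with Spearman's rho, 0.559, 0.508 and 0.463 for genes at 10 FPKM or more, and 0.705, 0.666 and 0.648 with no filter. The order of the 3 held in each. Averages of 5 splits gave 0.610, 0.619 and 0.542 with a pseudocount of 0.1 and 0.705, 0.625 and 0.541 at 10 FPKM or more. The median CV became 1.15 with TPM and 1.18 with size factors in the numbered set, and 1.70 and 1.85 in the numbered and unnumbered sets at 1 FPKM or more. In the unnumbered set it was 1.35 without splits 247 and 253, and 1.39 to 1.46 when 1 library was left out, the lowest without split 253. Lists with low CV in the unnumbered set fell from 2 to 1 with the SD of log2 values. Genes differing between sets numbered 359 with runs b, c and d, which tests fewer libraries, 319 for protein-coding genes, which tests fewer genes, and 953 by the exact rank-sum test, and 486 to 607 when 1 library was left out. Between runs a and b the count was 0 with a pseudocount of 0.1, at 5 FPKM or more, with size factors and without split 9, 5 with no filter, and 0 to 1 when 1 library was left out. The rank-sum test also gave 0, but with a smallest p of 0.00476 it could hardly call any gene. Among named genes, TMSB4XP6 was past the threshold in both directions, and the other reversed values had not passed. With the length trend removed TMSB4XP6 became -1.04, PTTG1 -0.30 and CTD-2012J19.2 -1.82. With run a as a covariate PSMA2 became 0.13, SNRPD1 -0.051 and AL353629.1 -0.040, and with size factors SNRPD1 became -0.15. Calls of named genes were lost for 4 with size factors, 6 with run a as a covariate and 11 with the length trend removed, and gained for 3 with size factors (CCR7, HNRNPA1 and HSPH1) and 3 with the length trend removed (CKS2, TPI1 and PSMB3). Depth limits what single splits show mainly in split 247, at 0.128 M fragments.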

Other observations

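The test of capture was chosen after the spread had been seen. Several genes of the fixed lists were listed at 0 in all 20 libraries, where a 0 can also be a failed estimate. Among them were the immediate early genes FOS, FOSB, JUN and DUSP1, the heavy chain genes IGHG1, IGHG2 and IGHG3, and the germinal centre factor gene BCL6. The heavy chain genes IGHA1 and IGHM averaged 725 and 98.3 FPKM over the 20 libraries. Genes of other lineages, such as CD14, CD3D, HBB and KRT5, were also listed at 0 throughout.

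The spread between splits fell with level at a slope of -0.455 (numbered) and -0.452 (unnumbered) of log10 CV on log10 FPKM between 30 and 1000 FPKM, near the slope of -0.5 for random counting. If random capture of few molecules were the whole cause, the spread would also predict the level at which 50% of genes reach FPKM 1. The predicted level was 2.78 times (jackknife SE 0.343) the observed median of 17.9 FPKM in the numbered splits and 2.90 times (SE 0.304) the observed 25.1 FPKM in the unnumbered splits. The same ratio was 0.994 and 0.881 in simulated random counts. The spread and the detection rates thus did not match. However, the prediction puts 1 molecule at 71.8 FPKM in the numbered and 104.8 FPKM in the unnumbered set, while detection was set at FPKM 1. Values below 1 molecule count as detected and lower the observed level, and the simulated counts held none. Too large a spread was therefore not separated from too frequent detection, and random capture as the whole cause of the spread stays open. A candidate explanation for an excess of spread, if there is one, is uneven amplification after capture, and another, if a set held more than 1 pool, is a difference between pools. Neither was tested.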
